A study of Mus musculus with 12 samples.

How the data were processed

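Liver RNA of 12 libraries (3 per group) was sequenced with paired-end reads. Per the series design text, the authors aligned reads to the mm10 mouse genome with TopHat 2.1.0, and the deposited table holds raw read counts per Ensembl gene, which the authors made with featureCounts 1.4.6. The authors used edgeR 3.18.1 for differential expression. The Ensembl release and the strandedness of counting were not stated, so reads of overlapping genes on opposite strands may be shared. Among the genes described, Plin4, Jun, Mogat1, Timp1, Cd74, Cyp2d9, Herpud1 and Srebf1 overlap another annotated gene, which for Plin4 had a mean count of 461 against 1152 for Plin4 itself. The values were checked to be whole counts, the libraries were checked to be distinct, and all 12 columns were used. The table lists 43346 genes, of which 17776 had 0 counts in every library, and 37 mitochondrial genes were at 0 in all libraries, so no mitochondrial share was computed. Replicates were not pooled, and the labels give no sequencing batch or date.

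Total counts per library were taken as the depth (18873092 to 31154930). Genes were filtered with edgeR's filterByExpr by group, which left 16283 genes, 13543 of them protein-coding, and libraries were scaled by the trimmed mean of M-values. One quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3, glmQLFit with robust settings and glmQLFTest) was fitted to all 12 libraries with 4 groups, so that the groups share 1 estimate of the spread. From it came 5 contrasts: FFC against chow in each genotype, knockout against wild type on each diet, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. SE was derived from the fitted log2 change and its test statistic. Principal components and rank correlations used log2 CPM with a prior count of 2.

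The model, the contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of 36 gene lists with 456 distinct genes, covering liver cell types, immune cells, lipid and bile acid metabolism, stress responses and possible contaminating tissues, 33 had at least 3 tested genes. The lists for exocrine pancreas, adipose tissue and skeletal muscle had 1 tested gene each and were not tested. Symbols Adgre1, Jchain, Plpp3 and Tkfc are listed in the table under the older names Emr1, Igj, Ppap2b and Dak. Lists were tested with camera (limma) on log2 CPM, which compares a list's genes with all others, at a preset correlation of 0.01, adjusted over the 33 lists of a comparison. A list's members were counted as past the test over all genes and again when adjusted over the list alone. Alternatives were camera with a correlation estimated from the data and fry, which tests whether a list's genes move on balance 1 way, or change in either direction. For genes at 0 in all libraries of a group a lower bound of the fold was computed from a floor of 3 counts over the group, and for 1 to 3 counts a ratio with its 95% counting interval.

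Named genes were chosen in each comparison by a rule. It took those past the threshold with an average log2 CPM of at least 2, an established symbol and levels that do not overlap between groups (this last condition was dropped for the interaction), up to 10 with the largest positive and 10 with the largest negative change, and up to 4 members with the lowest p of each list described. S1pr1, Lyz2, Ccr2, Adgre1, Clec4f, Trem2, Gpnmb, Spp1, Col1a1, Timp1, Tnf and Ccl2 were always carried through the alternatives. Not all of them are described with their levels in the text.

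Alternatives for genes and lists were median-ratio size factors, no filter on low counts, the authors' stated filter (protein-coding genes with an RPKM of at least 1 in at least 1 library), a term for the replicate number, a fit of the 2 compared groups alone (not for the interaction), and each library left out in turn. For genes alone they also were DESeq2 1.42.0 and limma-voom and, for the counts of genes, an adjusted p under 0.1 and an unadjusted p of at most 0.05 with a log2 change of at least 0.5. For the genotype comparison on FFC an unadjusted p of at most 0.5 was also tried, since the series design text gives that threshold. Later additions were offsets from spline trends (4 degrees of freedom) of each library's log2 CPM on GC content and transcript length, known for 99.06% of tested genes, voom with library quality weights (genes alone), counts thinned to 18873092 per library, and list tests in 2 groups alone. Genes detected were also counted after thinning to 15189064 counts of total times normalization factor. The pipeline was tested on simulated data with the genotype comparison on FFC. The changed genes were drawn only from well-counted genes, so recovery over all tested genes may be lower. A recovered gene had to change in the right direction in the fit of all groups, but not in the fit of 2 groups. With 200 genes changed 2-fold the fit of all groups recovered 44% with 2 false calls and the fit of 2 groups 88.5% with 13, and with 4-fold changes they recovered 98% with 1 false call and 97.5% with 16. Exon-level reads, transcript isoforms and genome alignments were not analysed here.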

Results

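Liver gene expression was measured by bulk RNA sequencing in 12 libraries, 3 in each of 4 groups set by genotype and diet. Knockout mice carried a loxP-flanked S1pr1, which encodes a receptor for the lipid mediator sphingosine 1-phosphate, together with Lyz2-Cre, a recombinase active in myeloid cells such as macrophages and neutrophils. Wild-type mice were littermates. Each genotype received either chow or a diet rich in fat, fructose and cholesterol (FFC) for 24 weeks from 12 weeks of age. Total counts per library were 21340263 to 22531709 in wild-type chow and 18873092 to 25855609 in knockout chow livers. They were 28415409 to 31154930 in wild-type FFC and 25773607 to 27652530 in knockout FFC livers. Of 43346 annotated genes, 16283 had enough counts to be tested. Levels are CPM, counts scaled to library size with the trimmed mean of M-values, given as mean ± SD over the n = 3 libraries of a group. Fold changes are log2 values from edgeR with their standard error (SE). The labels do not state that each library came from its own mouse, so every p-value refers to the spread between these libraries.

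S1pr1 (ENSMUSG00000045092, protein-coding, chromosome 3, 115710433 to 115715055 in mm10) was counted in every library. Its level was 29.8, 27.3 and 44.4 CPM in wild-type chow replicates 2, 3 and 4, and 41.5, 28.2 and 32.9 CPM in knockout chow replicates 1, 2 and 3. In wild-type FFC replicates 2, 3 and 4 it was 33.7, 39.3 and 29.1 CPM, and in knockout FFC replicates 1, 4 and 7 it was 35.4, 35.8 and 39.0 CPM. The knockout to wild-type log2 difference was 0.11 (SE 0.20, edgeR adjusted p = 1.00) on FFC and 0.02 (edgeR adjusted p = 0.971) on chow, and neither passed the test. Whole liver also holds cells without Lyz2-Cre that express S1pr1, and counts per gene do not resolve the floxed exon, so these values test the genotype labels only in part. Lyz2, the lysozyme gene whose locus drives the Cre, stood at 52.0 ± 5.71 CPM in wild-type and 46.8 ± 7.20 CPM in knockout chow livers (n = 3 each). On FFC it stood at 177 ± 12.6 and 125 ± 33.9 CPM, and neither genotype difference passed the test. The FFC levels did not overlap (162.6 to 185.9 CPM in wild-type and 92.25 to 160 CPM in knockout libraries), as for 21.3% of all tested genes. Among 18 measured genes of sphingosine 1-phosphate receptors, synthesis and breakdown, 0 passed the edgeR test between genotypes on FFC (median log2 change 0.05, camera adjusted p = 0.897). Of all 16283 tested genes 3 passed the same test.

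The first principal component of log2 expression (41.9% of the variance) separated the diets, and the second (14.0%) set knockout chow replicate 1 apart from the other libraries. Rank correlations within a group were 0.950 to 0.964 in knockout chow, 0.970 to 0.977 in wild-type chow, 0.983 to 0.985 in knockout FFC and 0.990 to 0.991 in wild-type FFC libraries, across genes, which are not independent replicates. The biological coefficient of variation was 0.331 in a fit of the chow libraries and 0.172 in a fit of the FFC libraries. Every chow library had fewer genes with at least 1 count (16008 to 19029) than any FFC library (20556 to 21308). After all libraries were thinned to the smallest total, the ranges were 16008 to 18866 and 20031 to 20695. Albumin, the main secreted protein of hepatocytes, took 7.31% of the counts in knockout chow replicate 1 and 10.1% to 14.3% in the other chow libraries.

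**Figure D1:**
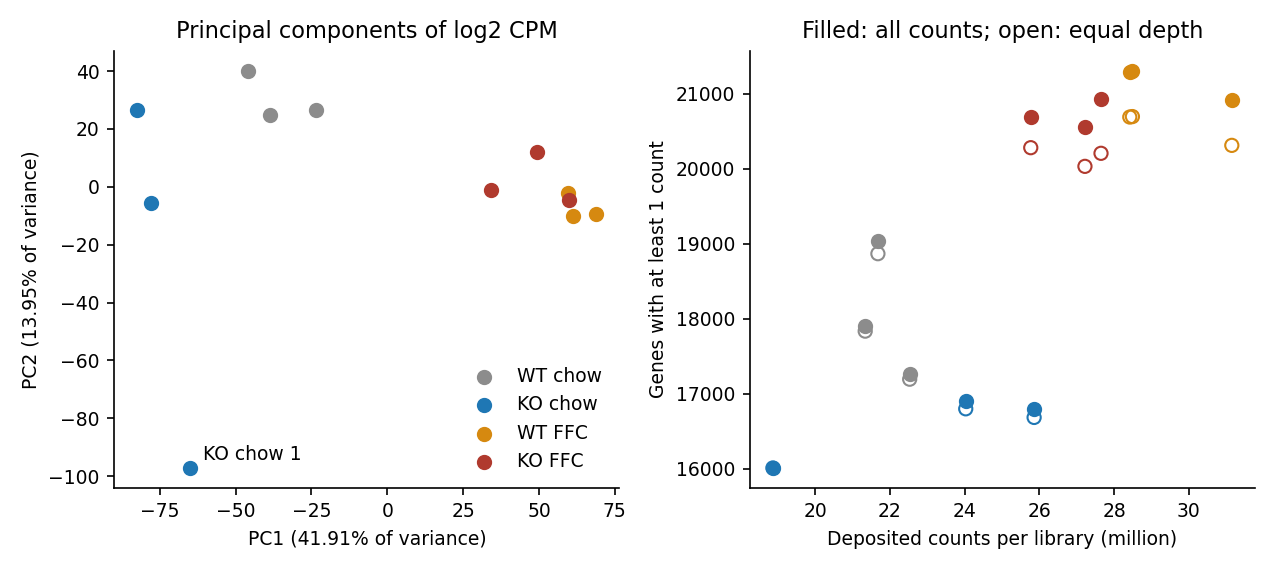
Left, the 12 libraries on principal components 1 and 2 of log2 CPM, coloured by group. Right, genes with at least 1 count against the total counts of each library, with filled points for all counts and open points after thinning to equal depth: every chow library lies below every FFC library in both.

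The FFC diet was compared with chow in wild-type liver to describe the response to the diet without the deletion. Genes of cholesterol synthesis were lower on FFC: of 22 measured, 19 fell and 3 did not pass (20 fell adjusted over the list alone, median log2 change -1.70, camera adjusted p = 4.3e-14, adjusted p = 0.124 with an estimated correlation). Sqle, which encodes squalene epoxidase, fell from 65.8 ± 10.7 to 3.93 ± 1.80 CPM (log2 change -4.06, SE 0.40, edgeR adjusted p = 1.9e-05). Idi1 and Cyp51, other enzymes of the pathway, fell with log2 changes of -3.43 and -2.84. Lipid droplet genes were higher: of 14 measured, 11 rose and 3 did not pass (12 rose adjusted over the list alone, median 1.60, camera adjusted p = 2.0e-09, adjusted p = 0.0645 with an estimated correlation). Cidec, which promotes droplet growth, rose from 2.21 ± 0.504 to 114 ± 7.35 CPM (log2 change 5.68, SE 0.37, edgeR adjusted p = 4.6e-07). Mogat1, an enzyme of triglyceride synthesis, rose from 1.28 ± 0.348 to 8.54 ± 1.63 CPM. Of 18 lipogenesis genes, 10 rose, 1 fell and 7 did not pass (13 rose and 2 fell adjusted over the list alone, median 0.79, camera adjusted p = 2.3e-04, adjusted p = 0.124 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose from 3670 ± 1725 to 35720 ± 3848 CPM (log2 change 3.28, SE 0.34, edgeR adjusted p = 1.9e-05). Of 18 genes of bile acid synthesis and transport, 8 fell, 2 rose and 8 did not pass (11 fell and 3 rose adjusted over the list alone, median -0.68, camera adjusted p = 1.1e-04, adjusted p = 0.171 with an estimated correlation). Cyp7b1, of the alternative synthesis pathway, fell from 354 ± 106 to 45.9 ± 11.6 CPM, and Slc10a1, the sodium-dependent bile acid uptake carrier, fell from 811 ± 76.5 to 284 ± 25.5 CPM. Of 14 genes of xenobiotic metabolism, 8 fell and 6 did not pass (8 fell and 1 rose adjusted over the list alone, median -0.70, camera adjusted p = 0.0016, adjusted p = 0.231 with an estimated correlation). Cyp1a2, a drug-metabolising cytochrome, fell from 649 ± 247 to 117 ± 37.5 CPM. With offsets for GC content and transcript length both lists kept their call, with medians of -0.45 for bile acid and -0.33 for xenobiotic metabolism genes. Of the called genes, 4 of 8 in xenobiotic metabolism, 8 of 10 in the bile acid list and 6 of 11 in lipogenesis kept their call with these offsets.

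Macrophage markers were higher on FFC in wild-type liver. Of 15 general macrophage markers, 14 rose (14 adjusted over the list alone, median log2 change 1.396, camera adjusted p = 3.7e-09, adjusted p = 0.112 with an estimated correlation). Adgre1, which encodes a surface receptor of mature macrophages, rose from 12.1 ± 1.83 to 34.0 ± 4.47 CPM (log2 change 1.49, SE 0.23, edgeR adjusted p = 4.5e-04). Of 11 markers of lipid-associated macrophages, 7 rose and 4 did not pass (9 rose adjusted over the list alone, median 2.27, camera adjusted p = 7.3e-06, adjusted p = 0.196 with an estimated correlation). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, rose from 0.377 ± 0.313 to 30.8 ± 6.29 CPM (log2 change 6.36, SE 0.53, edgeR adjusted p = 1.0e-05). Mmp12, macrophage elastase, rose from 0.527 ± 0.258 to 39.3 ± 9.37 CPM (log2 change 6.22, SE 0.65, edgeR adjusted p = 8.3e-05). Of 12 markers of monocyte-derived cells, 6 rose and 6 did not pass (9 rose adjusted over the list alone, median 2.18, camera adjusted p = 2.9e-05, adjusted p = 0.124 with an estimated correlation). Of 18 cytokine, chemokine and adhesion genes, 6 rose and 12 did not pass (9 rose adjusted over the list alone, median 1.10, camera adjusted p = 1.1e-05, adjusted p = 0.0645 with an estimated correlation). The leukocyte adhesion receptor Vcam1 rose from 9.50 ± 4.58 to 37.0 ± 9.39 CPM. Of 17 interferon response genes, 8 rose and 9 did not pass (8 adjusted over the list alone, median 0.88, camera adjusted p = 8.4e-05, adjusted p = 0.193 with an estimated correlation). Of 7 genes of MHC class II antigen presentation, 5 rose and 2 did not pass (7 rose adjusted over the list alone, median 1.77, camera adjusted p = 8.7e-05, adjusted p = 0.196 with an estimated correlation). Cd74, the invariant chain, rose from 42.0 ± 4.19 to 150.5 ± 14.0 CPM. Of 9 dendritic cell markers, 3 rose and 6 did not pass (5 rose adjusted over the list alone, median 1.62, camera adjusted p = 8.1e-04, adjusted p = 0.0645 with an estimated correlation).

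Markers of other liver cells also moved with the diet in wild-type liver. Of 18 genes of stellate cells and fibrosis, 16 rose and 2 did not pass (16 adjusted over the list alone, median log2 change 1.98, camera adjusted p = 7.4e-09, adjusted p = 0.124 with an estimated correlation). Col1a2, a chain of type I collagen, rose from 2.88 ± 0.687 to 23.6 ± 6.53 CPM (log2 change 3.04, SE 0.49, edgeR adjusted p = 0.0011). Pdgfrb, a growth factor receptor of stellate cells, rose from 2.37 ± 0.575 to 12.1 ± 2.61 CPM. Of 13 endothelial markers, 7 rose and 6 did not pass (11 rose adjusted over the list alone, median 0.71, camera adjusted p = 2.9e-05, adjusted p = 0.159 with an estimated correlation). Lyve1, a hyaluronan receptor of sinusoidal endothelium, rose from 4.92 ± 3.55 to 24.2 ± 6.86 CPM. Of 15 cell cycle genes, 6 rose and 9 did not pass (6 adjusted over the list alone, median 1.402, camera adjusted p = 0.0017, adjusted p = 0.196 with an estimated correlation). Of 12 hepatocyte markers, 8 fell and 4 did not pass (8 adjusted over the list alone, median -0.95, camera adjusted p = 7.3e-06, adjusted p = 0.0954 with an estimated correlation). Ahsg, the secreted protein fetuin-A, fell from 8215 ± 778 to 3612 ± 733 CPM (log2 change -1.18, SE 0.18, edgeR adjusted p = 4.1e-04). Of 15 genes of the endoplasmic reticulum stress response, 4 fell and 11 did not pass (5 fell adjusted over the list alone, median -0.49, camera adjusted p = 0.0045, adjusted p = 0.289 with an estimated correlation). Of 9 male-biased genes, 3 fell and 6 did not pass (3 adjusted over the list alone, median -0.69, camera adjusted p = 0.0013, adjusted p = 0.112 with an estimated correlation). Cyp2d9, a male-biased cytochrome, fell from 1493 ± 98.9 to 603 ± 237 CPM. With offsets for GC content and transcript length the medians were -0.24 for male-biased genes and -0.60 for hepatocyte markers, and both lists kept their call. Of the called genes, 5 of 7 endothelial, 14 of 16 stellate cell and fibrosis and 4 of 6 cell cycle genes kept their call with these offsets. At equal depth the wild-type chow libraries had 17192 to 18866 genes with at least 1 count and the wild-type FFC libraries 20311 to 20695.

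The edgeR test called 2734 genes between the diets in wild-type liver, 1427 higher and 1307 lower on FFC, and 1569 of these changed more than 2-fold. The 3 FFC and 3 chow levels did not overlap for 45.1% of all tested genes, where chance gives 10%. The count was 1682 without wild-type chow replicate 3, 1756 without wild-type chow replicate 4, and 1305, 1565 and 1488 without wild-type FFC replicates 2, 3 and 4. In 57 genes every library of 1 group was at 0, and 41 of these were called, all 41 of them at 0 on chow. Their folds are lower bounds from a floor of 3 counts over the group, and such bounds and all counting intervals cover counting error only. For each of the 18 called lists the estimated-correlation p was the highest under any alternative and the lowest lay between 3.5e-19 and 5.1e-04. Beside it 1 alternative ended a call, that of the cell cycle list with the authors' expression filter (adjusted p = 0.0515). Other groupings of the same 6 libraries gave 6 to 16 lists by camera, where the real one gave 18, and 0 genes by edgeR. Kupffer cell markers went both ways in wild-type liver, with 4 of 14 higher, 2 lower and 8 not past the test (7 higher and 4 lower adjusted over the list alone, median 0.39, camera adjusted p = 0.421).

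The same comparison in knockout liver asked how livers with S1pr1 deleted in myeloid cells respond to the diet. Of 22 cholesterol synthesis genes, 19 fell and 3 did not pass (20 fell adjusted over the list alone, median log2 change -1.77, camera adjusted p = 2.1e-12, adjusted p = 0.265 with an estimated correlation). Mvk, mevalonate kinase, fell from 32.5 ± 14.7 to 5.05 ± 0.513 CPM (log2 change -2.69, SE 0.26, edgeR adjusted p = 1.5e-05). Of 14 lipid droplet genes, 10 rose, 1 fell and 3 did not pass (10 rose and 1 fell adjusted over the list alone, median 1.21, camera adjusted p = 3.0e-04, adjusted p = 0.196 with an estimated correlation). Cidec rose from 5.33 ± 3.06 to 65.1 ± 9.20 CPM (log2 change 3.61, SE 0.33, edgeR adjusted p = 1.4e-05). Cd36, a fatty acid uptake receptor, rose from 87.7 ± 32.3 to 239.9 ± 51.3 CPM. Of 12 hepatocyte markers, 10 fell and 2 did not pass (12 fell adjusted over the list alone, median -0.96, camera adjusted p = 4.9e-06, adjusted p = 0.169 with an estimated correlation). Apoa1, the main protein of high-density lipoprotein, fell from 15670 ± 3762 to 5347 ± 311 CPM (log2 change -1.55, and -0.84 with offsets for GC content and transcript length). Of 14 xenobiotic metabolism genes, 7 fell and 7 did not pass (8 fell adjusted over the list alone, median -0.73, camera adjusted p = 0.0022, adjusted p = 0.331 with an estimated correlation). Of 15 endoplasmic reticulum stress genes, 5 fell and 10 did not pass (5 adjusted over the list alone, median -0.60, camera adjusted p = 0.0030, adjusted p = 0.341 with an estimated correlation). The median of that list was -0.27 with the offsets, and its call was kept. Herpud1, a component of protein quality control, fell from 583 ± 178 to 289.9 ± 66.6 CPM. Of 11 acute phase genes, 5 fell and 6 did not pass (5 adjusted over the list alone, median -1.25, camera adjusted p = 0.016, adjusted p = 0.511 with an estimated correlation). The list lost its call without knockout chow replicate 2 (adjusted p = 0.0949) and without knockout FFC replicate 7 (adjusted p = 0.0749). It also lost it with a term for the replicate number (adjusted p = 0.161) and by fry (adjusted p = 0.136).

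Macrophage and inflammatory genes were also higher on FFC in knockout liver. Of 15 general macrophage markers, 11 rose and 4 did not pass (11 adjusted over the list alone, median log2 change 1.26, camera adjusted p = 1.3e-05, adjusted p = 0.265 with an estimated correlation). Cybb, the phagocyte oxidase subunit, rose from 7.93 ± 2.24 to 36.2 ± 6.77 CPM (log2 change 2.19, SE 0.25, edgeR adjusted p = 4.0e-05). Of 12 markers of monocyte-derived cells, 7 rose and 5 did not pass (8 rose adjusted over the list alone, median 2.08, camera adjusted p = 0.0031, adjusted p = 0.328 with an estimated correlation). Of 11 markers of lipid-associated macrophages, 5 rose and 6 did not pass (9 rose adjusted over the list alone, median 1.47, camera adjusted p = 0.0072, adjusted p = 0.511 with an estimated correlation). Gpnmb was not counted in knockout chow livers and stood at 12.6 ± 7.40 CPM on FFC, at least 231.5-fold higher (edgeR adjusted p = 1.5e-05). Of 18 cytokine, chemokine and adhesion genes, 9 rose and 9 did not pass (10 rose adjusted over the list alone, median 1.42, camera adjusted p = 0.0019, adjusted p = 0.196 with an estimated correlation). Of 17 interferon response genes, 10 rose and 7 did not pass (10 adjusted over the list alone, median 1.15, camera adjusted p = 6.5e-04, adjusted p = 0.328 with an estimated correlation). Of 7 MHC class II genes, 4 rose and 3 did not pass (6 rose adjusted over the list alone, median 1.34, camera adjusted p = 0.0067, adjusted p = 0.511 with an estimated correlation). Of 9 dendritic cell markers, 3 rose and 6 did not pass (4 rose adjusted over the list alone, median 1.66, camera adjusted p = 0.0040, adjusted p = 0.169 with an estimated correlation). The median was 2.01 for MHC class II genes with offsets for GC content and length in the knockout libraries alone, and 3.12 for dendritic cell markers with the replicate term. Of 15 cell cycle genes, 8 rose and 7 did not pass (10 rose adjusted over the list alone, median 1.80, camera adjusted p = 6.5e-04, adjusted p = 0.265 with an estimated correlation). Mcm2, a replication helicase subunit, rose from 1.85 ± 0.914 to 6.46 ± 1.27 CPM. Of 18 stellate cell and fibrosis genes, 8 rose and 10 did not pass (8 adjusted over the list alone, median 0.91, camera adjusted p = 0.019, adjusted p = 0.511 with an estimated correlation). The list lost its call without knockout chow replicate 3 (adjusted p = 0.0863) and without knockout FFC replicate 1 (adjusted p = 0.0770). Of 5 erythroid genes, 2 fell and 3 did not pass (3 fell adjusted over the list alone, median -0.97, camera adjusted p = 0.045, adjusted p = 0.511 with an estimated correlation). That call was lost without wild-type chow replicate 3 (0.0570), knockout chow replicates 1 (0.133) and 2 (0.0969) or knockout FFC replicate 4 (0.0948). It was lost as well with median-ratio factors (0.05004), with the authors' expression filter (0.0615), by fry (0.0998) and with the offsets, where the median was -0.24 (0.379) or, in the knockout libraries alone, -0.21 (0.350). The median was -1.48 with the replicate term and -0.65 without knockout chow replicate 2. At equal depth the knockout chow libraries had 16008 to 16797 genes with at least 1 count and the knockout FFC libraries 20031 to 20280.

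The edgeR test called 4312 genes between the diets in knockout liver, 2231 higher and 2081 lower on FFC, and 2307 of these changed more than 2-fold. The levels did not overlap for 39.5% of all tested genes, where chance gives 10%. The count was 2751 without knockout FFC replicate 1, 2814 without knockout FFC replicate 4, and 2351 when the knockout libraries were fitted alone. In 210 genes every library of 1 group was at 0, and 184 of these were called, all 184 of them at 0 on chow. For each of the 16 called lists the estimated-correlation p was the highest under any alternative, and the lowest lay between 1.4e-17 and 0.0091. Other groupings of the same 6 libraries gave 3 to 11 lists by camera, where the real one gave 16. Of 18 lipogenesis genes, 6 rose, 1 fell and 11 did not pass (9 rose and 3 fell adjusted over the list alone, median 0.46, camera adjusted p = 0.0785). Of 14 Kupffer cell markers, 6 rose and 8 did not pass (7 rose adjusted over the list alone, median 0.44, camera adjusted p = 0.0778). Marco, a scavenger receptor, rose from 12.3 ± 3.52 to 41.7 ± 13.4 CPM. Of 13 endothelial markers, 5 rose and 8 did not pass (5 rose and 1 fell adjusted over the list alone, median 0.50, camera adjusted p = 0.290). With offsets for GC content and length 2 of the 5 kept their call, and Tek went from 0.88 to 0.49 (adjusted p = 0.0523), Stab2 from 0.72 to 0.33 (0.0664) and Kdr from 0.66 to 0.22 (0.325). Of the called genes, 5 of 8 of stellate cells and fibrosis, 5 of 8 of the cell cycle and 0 of 2 erythroid genes kept their call with these offsets. Of 18 bile acid genes, 4 fell, 2 rose and 12 did not pass (4 fell and 2 rose adjusted over the list alone, median -0.26, camera adjusted p = 0.0778).

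The diet effects of both genotypes were set side by side across genes. Of the genes called higher on FFC, 706 were called higher in both genotypes, where independent calls would share 195.5, and 869 were called lower in both, where independent calls would share 167. In all, 1584 genes were called in both genotypes and 9 of them went in opposite directions. Pearson's r between the effects was 0.546 over 16283 genes and 0.637 over the 5462 genes called in either genotype, and genes are not independent replicates. The diet effect in wild type was also correlated with the genotype effect on FFC (r = -0.432, covariance -0.184), a pair of contrasts that share the wild-type FFC libraries. In 20 simulations without any group difference that pair gave r from -0.304 to -0.266 and a covariance from -0.0548 to -0.0468. The simulations drew each gene independently, without the GC content and length trends of the real libraries. The range without a difference may therefore be wider in the real data. With 3 shared libraries the controls were not divided between the contrasts, so how much of the difference comes from them was not measured.

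**Figure D2:**
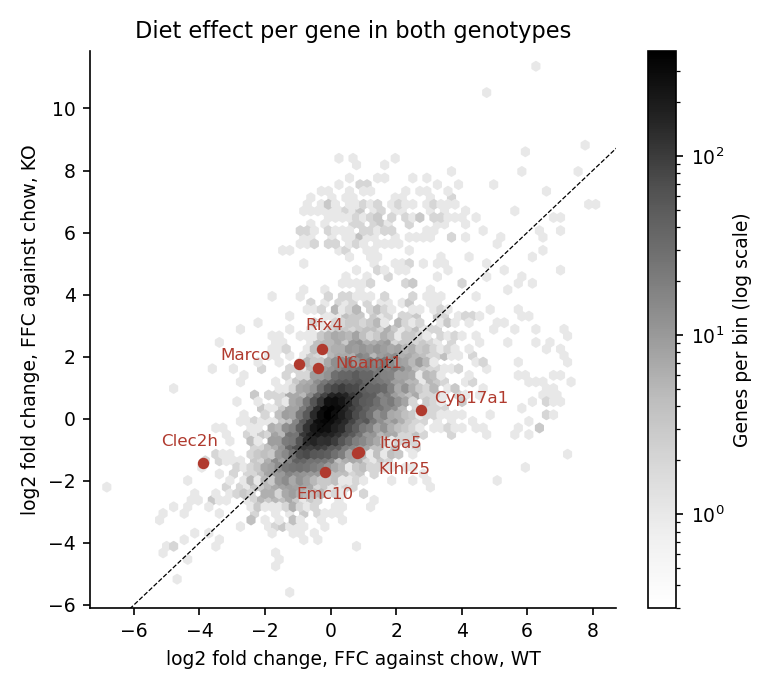
Log2 change on FFC in knockout liver (vertical) against wild-type liver (horizontal) for the 16283 tested genes, as a density with a logarithmic colour scale and a dashed line of equality. The 8 genes past the threshold in the test of the difference are marked in red, and Marco and Cyp17a1 lie on opposite sides of the line.

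Knockout and wild-type livers were compared on FFC, the comparison that the series design text describes, to ask what loss of S1pr1 in myeloid cells changes under the diet. Markers of resident Kupffer cells, the macrophages of the liver sinusoids, were higher in knockout livers, with a positive log2 change in 14 of 14 (median 0.55, camera adjusted p = 2.4e-12). The list had an adjusted p = 0.0751 with an estimated correlation, the highest under any alternative, and the lowest was 4.0e-14. The median was 0.31 with a term for the replicate number. Of the 14, 2 rose in the test over all genes and 6 adjusted over the list alone. Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), a scavenger receptor of macrophages, rose from 6.48 ± 2.27 to 41.7 ± 13.4 CPM (log2 change 2.69, SE 0.32, edgeR adjusted p = 0.0022). Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), a phosphatidylserine receptor of embryonic-derived Kupffer cells, rose from 4.38 ± 0.695 to 14.4 ± 1.74 CPM (log2 change 1.72, SE 0.25, edgeR adjusted p = 0.018). The Kupffer cell lectin Clec4f stood at 130 ± 14.6 in wild-type and 168 ± 14.0 CPM in knockout livers. The complement receptor Vsig4 stood at 44.4 ± 4.08 and 70.7 ± 15.4 CPM, and neither gene passed the test over all genes (edgeR adjusted p = 1.00 for both). Cyp17a1 (ENSMUSG00000003555, chromosome 19, 46667165 to 46672974), a steroid hydroxylase, fell from 31.5 ± 9.11 to 8.62 ± 3.38 CPM (log2 change -1.87, SE 0.30, edgeR adjusted p = 0.047). These 3 protein-coding genes were the only ones called by edgeR in the main fit of all groups, while 591 had an unadjusted p under 0.05. That fit shares its spread with the chow libraries, which varied more (biological coefficient of variation 0.331 against 0.172 in FFC libraries). In simulated data it recovered 44% of genes changed 2-fold between genotypes on FFC, with 2 false calls. The fit of 2 groups recovered 88.5% with 13, so the low count does not show that few genes differed. The levels did not overlap for 21.3% of all tested genes, where chance gives 10%.

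**Figure D3:**
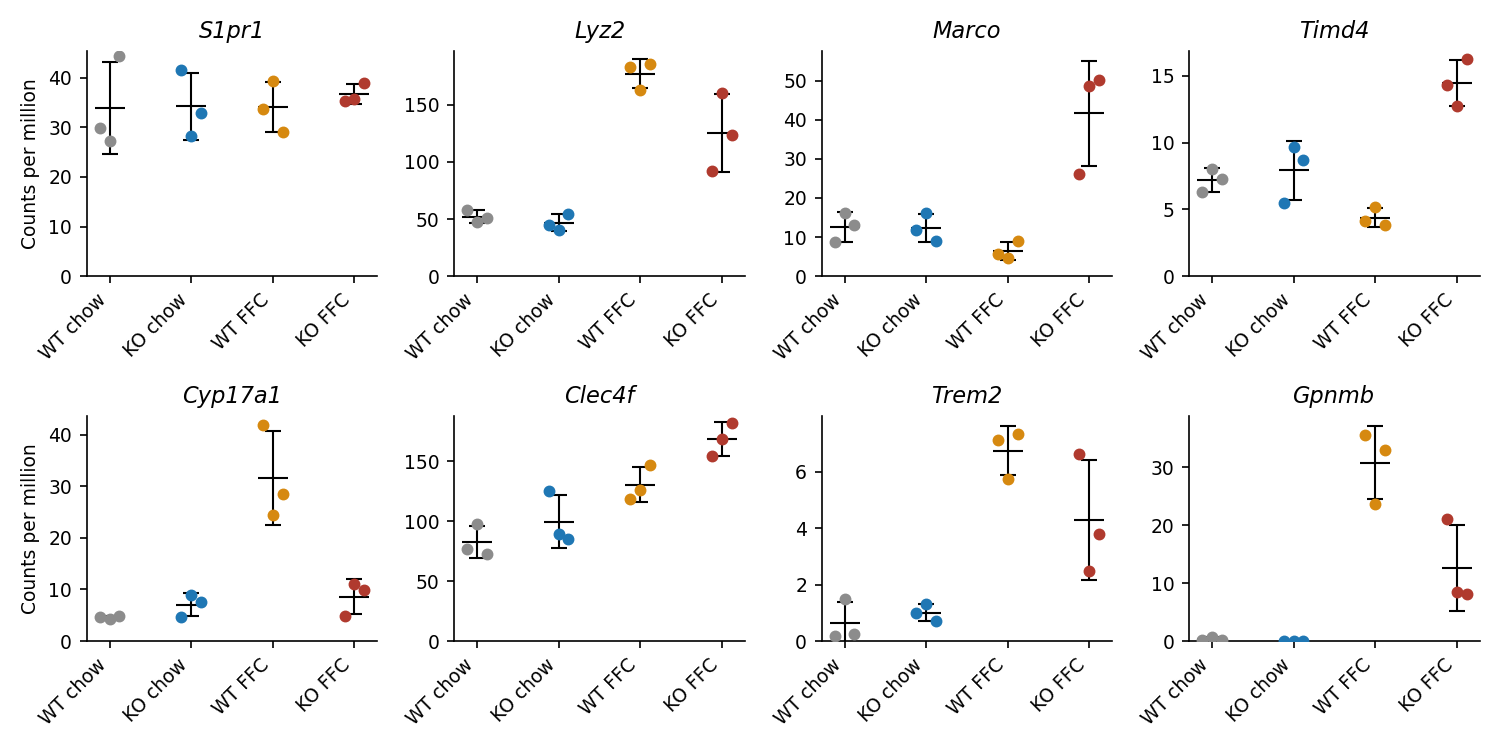
CPM of S1pr1, Lyz2, Marco, Timd4, Cyp17a1, Clec4f, Trem2 and Gpnmb in each library of the 4 groups, with the mean and SD of 3 libraries and every axis starting at 0. Marco and Timd4 are higher in the 3 knockout FFC libraries than in the 3 wild-type FFC libraries, and the S1pr1 levels overlap between genotypes.

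The call of Marco depended on the fit, that of Timd4 on the libraries and that of Cyp17a1 on both. Marco kept its call with any 1 library left out but was not past the threshold when the FFC libraries were fitted alone (adjusted p = 0.0955, range over alternatives 3.8e-25 to 0.1003). Timd4 lost its call without wild-type FFC replicates 2 (adjusted p = 0.286), 3 (0.0526) and 4 (0.137) and knockout FFC replicates 1 (0.117) and 7 (0.205), with a range over alternatives of 3.6e-08 to 0.286. Cyp17a1 lost its call without wild-type chow replicates 2 (adjusted p = 0.104), 3 (0.0970) and 4 (0.104), and knockout chow replicate 3 (0.0761). It also lost it without wild-type FFC replicates 2 (0.467), 3 (0.0526) and 4 (0.133) and knockout FFC replicates 1 (0.193) and 7 (0.205), with a range over alternatives of 1.3e-10 to 0.467. The number of called genes was 1 without each wild-type FFC library and without knockout FFC replicates 1 and 7, and 5 without knockout FFC replicate 4. A fit of the FFC libraries alone called 17 genes, of which 1, Timd4, was shared. Among the other 16, which the fit of all groups did not call and which were chosen for mention after their values were seen, were Jun, Plin4, Cidec, Scd2 and Dusp1, lower in knockout livers with log2 changes of -1.58, -1.43, -0.82, -1.12 and -0.92. Wfdc17 and Cfp were higher, with 1.33 and 0.85.

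Other gene groups also differed between genotypes on FFC by camera, without any member past the edgeR threshold over all genes. Of 18 bile acid genes, 16 had a positive log2 change (median 0.31, camera adjusted p = 6.2e-06, adjusted p = 0.286 with an estimated correlation, range over alternatives 2.8e-08 to 0.336). Of these 3 rose adjusted over the list alone, namely Cyp8b1, Cyp7b1 and Slc10a1. Cyp8b1, which sets the share of cholic acid, stood at 173 ± 31.7 CPM in wild-type and 348 ± 85.9 CPM in knockout livers. The median of the list was 0.18 without knockout FFC replicate 7. Of 12 hepatocyte markers, 9 had a positive change (median 0.26, camera adjusted p = 0.0739), and the list did not pass. Of 9 male-biased genes, 9 had a positive change (median 0.20, mean 0.71, camera adjusted p = 0.0072, adjusted p = 0.286 with an estimated correlation, range 9.4e-05 to 0.336). Of these 1, Cyp2d9, rose adjusted over the list alone, and the list lost its call without knockout FFC replicate 7 (0.0524) and without wild-type FFC replicate 2 (0.0526). It was also lost with the replicate term (0.126), in the FFC libraries alone (0.0513) and there with offsets (0.0758). Its median was 0.51 without wild-type FFC replicate 3, 0.35 without knockout FFC replicate 4 and 0.11 without knockout FFC replicate 7. Lipid-associated macrophage markers had a negative change in 11 of 11 (median -0.56, camera adjusted p = 1.4e-04, adjusted p = 0.420 with an estimated correlation, range 3.2e-06 to 0.543). With a term for the replicate number this median was -0.20 and the call was lost (0.378). Gpnmb, the 1 gene that fell adjusted over the list alone, stood at 30.8 ± 6.29 in wild-type and 12.6 ± 7.40 CPM in knockout livers. Endothelial markers had a positive change in 1 of 13 (median -0.35, camera adjusted p = 6.2e-06, adjusted p = 0.286 with an estimated correlation, range 1.8e-07 to 0.336). Lyve1, the 1 that fell adjusted over the list alone, stood at 24.2 ± 6.86 and 10.5 ± 1.99 CPM. Stellate cell and fibrosis genes had a positive change in 2 of 18 (median -0.42, camera adjusted p = 7.5e-05, adjusted p = 0.420 with an estimated correlation, range 2.5e-11 to 0.543), and 0 passed adjusted over the list alone in edgeR. This median was -0.24 without wild-type FFC replicate 2, -1.22 without knockout FFC replicate 1 and -0.15 without knockout FFC replicate 7. MHC class II genes had a negative change in 7 of 7 (median -0.55, camera adjusted p = 0.0072, adjusted p = 0.420 with an estimated correlation, range 5.3e-04 to 0.543). That call was lost without knockout FFC replicate 7 (0.144, median -0.33), and the median was -0.90 with the replicate term. Immediate early genes had a positive change in 2 of 9 (median -0.49, camera adjusted p = 0.047, adjusted p = 0.472 with an estimated correlation, range 0.0020 to 0.543). Jun, a transcription factor, fell adjusted over the list alone. The call was lost without wild-type chow replicate 4 (0.0635), wild-type FFC replicate 4 (0.155), knockout chow replicate 3 (0.0687) and knockout FFC replicates 4 (0.179, median -0.28) and 7 (0.119). It was also lost without the low-count filter (0.0605) and with offsets for GC content and length (0.0518), and the median was -1.16 with the replicate term. By fry in 1 direction the Kupffer list alone passed on FFC (0.0169), and each of the other 7 lists lost its call (0.336 to 0.543). Other groupings of the same 6 libraries gave 4 to 13 lists by camera, where the real one gave 8. General macrophage markers had a positive change in 9 of 15 (median 0.12, camera adjusted p = 0.167), and markers of monocyte-derived cells in 5 of 12 (median -0.12, camera adjusted p = 0.209), and neither list passed the test. Of 18 cytokine, chemokine and adhesion genes, 5 had a positive change (median -0.29, camera adjusted p = 0.130), and of 17 interferon response genes 8 did (median -0.12, camera adjusted p = 0.639). Of 14 lipid droplet genes, 5 had a positive change (median -0.15, camera adjusted p = 0.0827), and of 13 glucose and fructose genes 9 did (median 0.19, camera adjusted p = 0.0739). The fructose kinase Khk and the fructose carrier Slc2a5 rose adjusted over the list alone.

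**Figure D4:**
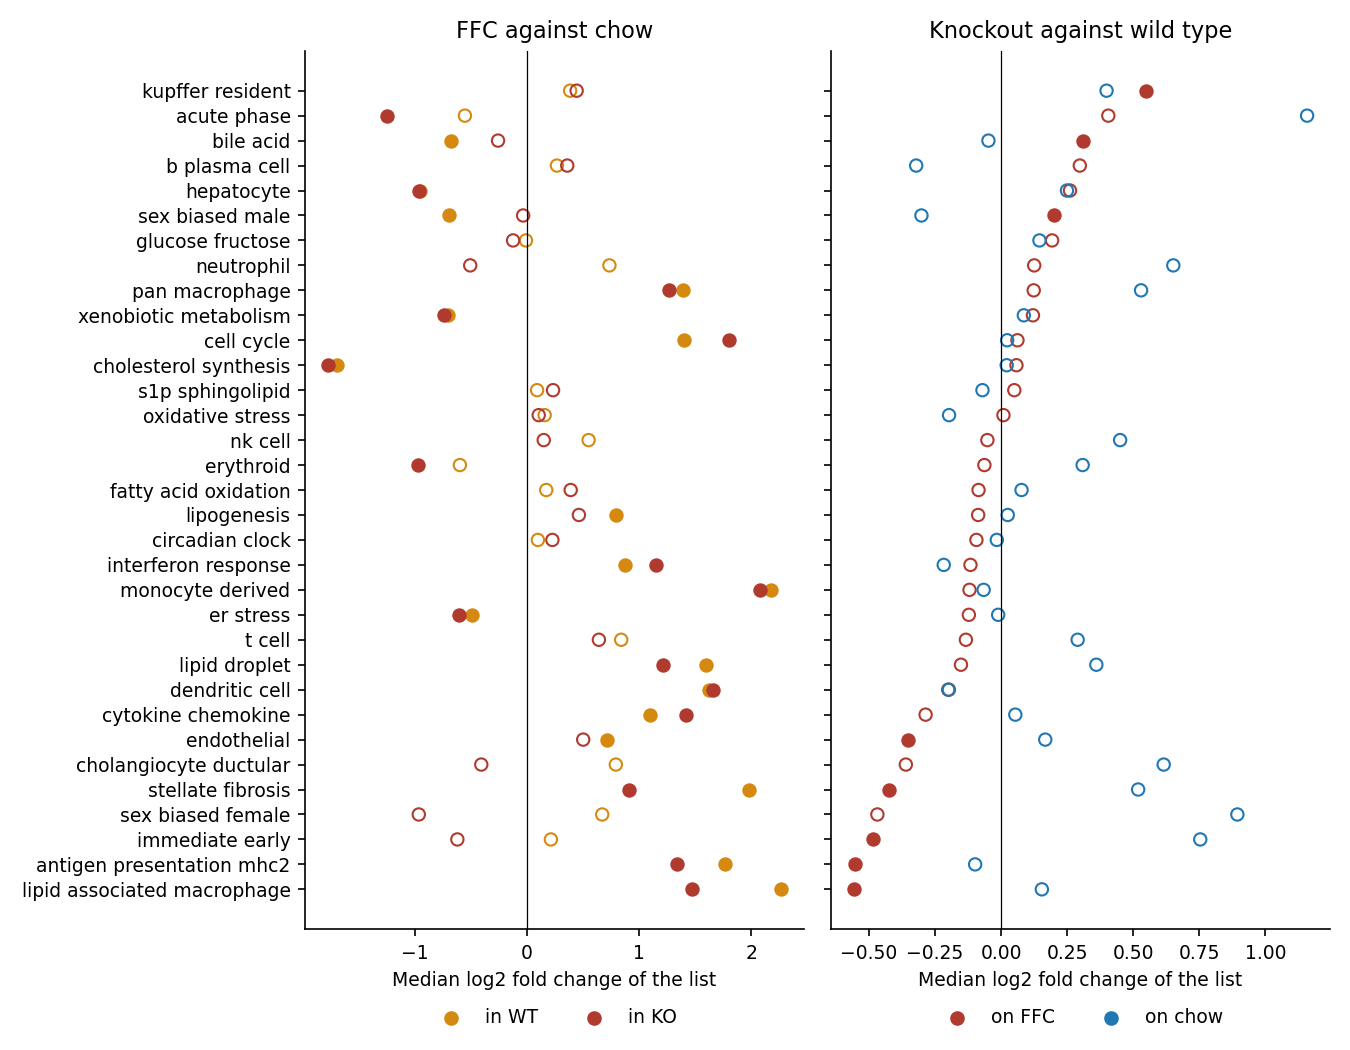
Median log2 change of the 33 tested gene lists, on the left for FFC against chow in wild-type and knockout liver and on the right for knockout against wild type on FFC and on chow. Filled points passed the camera threshold with its preset correlation and open points did not. Kupffer cell markers have the highest median change between genotypes on FFC, 0.55.

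Knockout and wild-type livers on chow were compared to describe the deletion without the diet. Of 18 lipogenesis genes, 5 rose in knockout livers and 13 did not pass (5 rose and 1 fell adjusted over the list alone, median log2 change 0.03, camera adjusted p = 0.706). Srebf1, a transcription factor of fatty acid synthesis, rose from 146 ± 34.0 to 306 ± 73.0 CPM (log2 change 1.07, SE 0.24, edgeR adjusted p = 0.023). Fasn, the fatty acid synthase, rose from 151 ± 21.9 to 346 ± 157 CPM (log2 change 1.20, SE 0.28, edgeR adjusted p = 0.024). Of 13 glucose and fructose genes, 4 rose and 9 did not pass (4 adjusted over the list alone, median 0.15, camera adjusted p = 0.204). Of 14 Kupffer cell markers, 2 rose and 12 did not pass (5 rose adjusted over the list alone, median 0.40, camera adjusted p = 0.0761). Lists that also did not pass were acute phase genes (11 of 11 positive, median 1.16, camera adjusted p = 0.102), general macrophage markers (11 of 15, 0.53, 0.204) and stellate cell and fibrosis genes (12 of 18, 0.52, 0.197). The acute phase gene Saa1 stood at 1158, 1049 and 39.9 CPM in knockout chow replicates 1, 2 and 3, and at 37.0, 567 and 76.9 CPM in wild-type chow replicates 2, 3 and 4. C1qb, a complement chain made by macrophages, rose from 34.9 ± 3.30 to 76.0 ± 25.4 CPM (log2 change 1.12, SE 0.21, edgeR adjusted p = 0.017). Of 13 endothelial markers, 2 rose, 1 fell and 10 did not pass (3 rose and 1 fell adjusted over the list alone, median 0.17, camera adjusted p = 0.653). With offsets for each library's GC content and transcript length trend 0 of the 5 called lipogenesis genes, 0 of the 4 glucose and fructose genes, 0 of the 2 Kupffer cell markers and 0 of the 3 endothelial markers kept their call. The log2 change of C1qa went from 0.92 to 0.19 (adjusted p = 0.529), that of Stab1 from 1.17 to 0.78 (0.0515) and that of Eng from 0.96 to 0.45 (0.152). Without knockout chow replicate 1 these were 0.60 (0.101), 0.73 (0.0764) and 0.64 (0.0997). Outside the lists, Itga5, the fibronectin receptor chain, rose from 9.05 ± 0.945 to 27.1 ± 9.51 CPM (log2 change 1.58, SE 0.24, edgeR adjusted p = 0.0093). Sik1, a salt-inducible kinase, rose from 6.69 ± 3.86 to 20.3 ± 1.43 CPM, and Rfx4 and N6amt1 fell from 5.00 ± 1.26 to 1.43 ± 0.220 and from 9.50 ± 2.11 to 3.17 ± 0.586 CPM. Called genes differed in base composition, with a median transcript GC content of 56.7% in genes higher in knockout livers, 46.0% in lower genes and 49.6% in all tested genes. Spearman's correlation of a library's deviations with GC content was 0.658 in knockout chow replicate 1 and -0.380 to 0.142 in the other chow libraries, and without that library the medians were 55.0% and 47.5%.

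The edgeR test called 1185 genes between genotypes on chow, 653 higher and 532 lower in knockout livers. A fit of the chow libraries alone called 0 of 14319, with 2283 at an unadjusted p under 0.05 and a lowest adjusted p of 0.067. With all libraries, DESeq2 called 2247, limma-voom 974 and voom with library quality weights 17. The edgeR count was 34, 690 and 514 without wild-type chow replicates 2, 3 and 4, 786 without knockout chow replicate 1 and 2533 without knockout chow replicate 3. It was 519, 514 and 502 without wild-type FFC replicates 2, 3 and 4, and 724 and 770 without knockout FFC replicates 1 and 7. With offsets for each library's GC content and transcript length trend 556 genes were called, of which 356 were shared. The offsets ended the calls of Srebf1 (adjusted p = 0.144, range over alternatives 6.3e-05 to 0.345), Fasn (0.161, range 5.6e-06 to 0.321) and C1qb (0.0747, range 2.4e-05 to 0.293). The log2 change of Srebf1 went from 1.07 (SE 0.24) to 0.60 (SE 0.22) and that of C1qb from 1.12 (SE 0.21) to 0.50 (SE 0.15), smaller changes, and that of Fasn from 1.20 (SE 0.28) to 0.90 (SE 0.34), a smaller change with a larger error. Without wild-type chow replicate 2 the adjusted p was 0.0855 for Srebf1, 0.0834 for Fasn and 0.0689 for C1qb. The call was also lost for Fasn without wild-type chow replicate 3 (0.0597) and knockout chow replicate 1 (0.0632), and for Srebf1 without wild-type chow replicate 4 (0.0626). Itga5, Sik1, Rfx4 and N6amt1 kept their call in every fit of all groups with 1 library left out. Camera called 0 of 33 lists on chow, where 4340 genes had an unadjusted p under 0.05 in edgeR and fry called 8 lists for change in either direction. The levels did not overlap for 20.6% of tested genes, where chance gives 10%, and in 255 genes every library of 1 group was at 0, with 63 of them called, 58 at 0 in knockout livers.

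Whether the diet effect differed between genotypes was tested as an interaction. It passed for 8 genes, 4 with a more positive diet effect in knockout liver and 4 with a more negative one (edgeR adjusted p = 0.0467 for each), out of 2625 with an unadjusted p under 0.05. For Marco the difference was 2.72 (SE 0.43), with levels of 12.6 ± 3.75 and 6.48 ± 2.27 CPM on chow and FFC in wild-type liver and 12.3 ± 3.52 and 41.7 ± 13.4 CPM in knockout liver. For Clec2h, a C-type lectin, it was 2.48 (SE 0.42), from a log2 change of -3.90 in wild-type and -1.42 in knockout liver. For Cyp17a1 it was -2.48 (SE 0.43), with levels of 4.62 ± 0.323 and 31.5 ± 9.11 CPM in wild-type and 7.05 ± 2.18 and 8.62 ± 3.38 CPM in knockout liver. Rfx4 (2.50), N6amt1 (2.00), Itga5 (-1.94), Klhl25 (-1.93) and Emc10 (-1.55) differed mainly between the chow groups, with genotype changes on chow of -1.81, -1.59, 1.58, 1.56 and 1.45. With offsets for GC content and length 5 of the 8 genes kept their call. Emc10 was among those that lost it, with a difference of -0.81 (edgeR adjusted p = 0.136). Among lists, stellate cell and fibrosis genes had a lower diet effect in knockout liver (median difference -0.72, 4 of 18 lower adjusted over the list alone, camera adjusted p = 0.0030, adjusted p = 0.820 with an estimated correlation, range from 1.5e-06). Endothelial markers did too (-0.31, 4 of 13 lower adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.820 with an estimated correlation, range from 0.0021). Their call was lost without wild-type chow replicate 2 (0.0806), knockout chow replicate 3 (0.0628) and knockout FFC replicate 4 (0.0606). Lipid droplet genes followed (-0.45, 1 of 14 lower adjusted over the list alone, camera adjusted p = 0.037, adjusted p = 0.820 with an estimated correlation, range from 0.012). Their call was lost without wild-type chow replicates 2 (0.0806) and 3 (0.0936), knockout chow replicates 1 (0.0981) and 3 (0.160), wild-type FFC replicate 3 (0.0632) and knockout FFC replicate 7 (0.120, median -0.29), and with offsets for GC content and length (0.111). All 3 lists lost their call with a term for the replicate number (0.0515 each) and by fry (0.543, 0.402 and 0.402). The gene count was 1, 0 and 0 without wild-type chow replicates 2, 3 and 4, and 96 and 580 without knockout chow replicates 2 and 3. It was 0, 0 and 1 without wild-type FFC replicates 2, 3 and 4, and 2, 1 and 0 without knockout FFC replicates 1, 4 and 7. It was 0 with limma-voom, 419 with DESeq2 and 0 after thinning to equal depth, and without knockout chow replicate 1 it was 8, of which 4 were shared.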

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

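The tests of the interaction for genes and for lists were fixed before the data were examined, and of the tests given here only the fits with quality weights and with thinned counts were chosen after the results were seen.

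The results here stood out because the diet effect differed between wild-type and knockout livers in a test of the difference itself. Marco had a difference of 2.72 on the log2 scale, the scavenger receptor being lower on FFC in wild-type livers and higher on FFC in knockout livers. Clec2h had a difference of 2.48, a smaller fall on FFC in knockout livers. Cyp17a1 had a difference of -2.48, a rise on FFC in wild-type livers (log2 change 2.77) against 0.29 in knockout livers. Rfx4 (2.50) and N6amt1 (2.00) were lower in knockout than in wild-type livers on chow. Emc10 (-1.55), Klhl25 (-1.93) and Itga5 (-1.94) were higher in knockout than in wild-type livers on chow. Over the alternatives the adjusted p of these 8 genes rose to 0.196 for 7 of them and to 0.200 for Cyp17a1, both without wild-type FFC replicate 2, and limma-voom, voom with quality weights and thinned counts left 0 of the 8 past the threshold. When genotype was relabelled at random within each diet, 1 of 100 relabelings, the real one, gave as many as 8 genes, and the highest of the others gave 3. Such relabelling tests for no genotype effect on either diet, not for equal diet effects. Mixed labels also add any genotype difference on chow to the spread, which can lower the other counts. The relabelings therefore cannot decide whether the diet effects differ.

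As groups, stellate cell and fibrosis genes (median difference -0.72), endothelial markers (-0.31) and lipid droplet genes (-0.45) had a lower diet effect in knockout livers by camera with its preset correlation, and 0 of the 3 passed with an estimated correlation (adjusted p = 0.820 for each). Lists passing in such numbers were common among the relabelings of genotype within each diet. Of 100 relabelings 67, the real one included, gave 3 or more lists, and the highest of the others gave 12. The number of lists therefore does not set the real labels apart. Relabelled libraries still hold any genotype effect, so these counts do not show what would arise without one.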

How the results depend on the processing

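The alternatives with GC and length offsets, with library quality weights, with counts thinned to equal depth and with list tests in 2 groups alone were chosen after the data were seen, and the others before. Leaving out a library leaves 2 in its group. Where no reason is given, the cause was not tested. Of 18 called lists in wild-type and 16 in knockout livers 0 held with an estimated correlation, nor did any of the 8 on FFC or the 3 of the interaction. Diet results kept their direction for all named genes except Mup20 and S1pr1 in wild-type and Hbb-bs and S1pr1 in knockout livers. The chow genotype and interaction results depended most on the setting. Depth limits genes at few counts, where the zero-count bounds apply, and the median gene shifted by less than 0.1 between scalings.

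Genes changed by diet in wild-type livers (2734) numbered 4174 with quality weights and 1305 to 3892 with 1 library left out. In knockout livers (4312) they numbered 2351 in the 2 groups alone, 2269 there with offsets and 2751 to 4977 with 1 library left out. Genes changed by genotype on FFC (3) numbered 114 without the filter, 18 with DESeq2, 85 with quality weights, 14 with the replicate term, 17 in the 2 groups alone, 16 there with offsets, 304 at an unadjusted p of at most 0.05 with the size threshold, 5411 at an unadjusted p of at most 0.5, and 1 to 5 with 1 library left out. Cyp17a1 was lost with median-ratio factors (adjusted p = 0.0524, range over alternatives 1.3e-10 to 0.467), which left 2, with thinned counts (0.0564) and with the replicate term (0.0503). Genes changed by genotype on chow (1185) numbered 1917 without the filter, 2247 with DESeq2, 17 with quality weights, 183 with the replicate term, 0 in the 2 groups alone, 556 with offsets, 0 with both, 2435 at an adjusted p under 0.1, 2767 at the unadjusted threshold, and 34 to 2533 with 1 library left out. Interaction genes (8) numbered 600 without the filter, 419 with DESeq2, 0 with voom, 0 with quality weights, 396 with the replicate term, 5 with offsets, 0 thinned, 89 at an adjusted p under 0.1, 1962 at the unadjusted threshold, and 0 to 580 with 1 library left out.

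Lists numbered 29 by fry in either direction for diet in knockout livers, 1 by fry in 1 direction and 1 in either for genotype on FFC (7 to 13 with 1 library left out), and, on chow, 2 without the filter, 3 with offsets, 1 in 2 groups with offsets, 8 by fry in either direction (0 to 3 left out). For the interaction they numbered 0 with the replicate term, 0 and 0 by fry, and 1 to 7 left out. With 1 library left out diet gave 18 to 21 lists in wild-type and 14 to 17 in knockout livers. The correlation of the diet effects (0.546) was 0.298 without the filter, 0.635 with the authors' filter, 0.610 with voom, 0.621 with quality weights, 0.603 in 2 groups, 0.625 there with offsets, 0.584 thinned and 0.461 to 0.522 with 1 library left out.

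Single genes that changed sign were mostly near 0 or at few counts. For diet in wild-type livers Mup20 gave 0.067 with offsets and 0.062 with offsets in 2 groups, and S1pr1 gave -0.0093 with median-ratio factors, -0.0093 with DESeq2, -0.0085 with quality weights, -0.00078 with offsets in 2 groups and -0.130 to 0.256 left out. For diet in knockout livers Hbb-bs gave 0.015 with offsets in 2 groups, and S1pr1 -0.099 with the replicate term, -0.083 with offsets, -0.067 with offsets in 2 groups and -0.047 to 0.266 left out. For genotype on FFC S1pr1 (0.107) gave -0.160 and Elovl3 -0.094 with the replicate term, and Col1a1 0.023 with offsets, 0.041 with offsets in 2 groups and -1.96 to 0.395 left out. Col1a1 stood at 17.8, 2.33 and 1.615 CPM in knockout FFC replicates 1, 4 and 7. In wild-type FFC replicates 2, 3 and 4 it stood at 9.95, 5.83 and 7.22 CPM. For genotype on chow S1pr1 gave -0.107 with quality weights, -0.023 with the replicate term and -0.149 to 0.260 left out, Lyz2 0.011 with the replicate term, Spp1 0.23 with quality weights and -0.614 to 0.647 left out, Timp1 -4.88 to 1.36 left out, Ccl2 -0.416 with quality weights and -0.585 to 3.76 left out, and Tnf -0.283 with voom, -1.005 with quality weights, -0.492 with the replicate term, -0.095 with offsets, -0.209 thinned and -3.92 to 1.33 left out. For the interaction S1pr1 gave -0.137 with the replicate term, -0.089 with offsets and -0.152 to 0.256 left out, Ccr2 -0.221 to 0.993 left out, Clec4f -0.051 with the replicate term and -0.066 to 0.290 left out, Spp1 0.317 with the replicate term and -1.20 to 0.109 left out, Timp1 -0.296 with voom, -0.754 with quality weights and -1.89 to 4.35 left out, and Tnf -0.510 to 4.73 left out. The labels do not say whether equal replicate numbers pair the libraries, and no clear pairing was seen. Deviations of the 10 same-numbered pairs correlated by -0.249 to 0.177, and those of the 44 others by -0.395 to 0.270. With 3 libraries per group these values cannot exclude a pairing. Of all comparisons of a single gene with an alternative, 7110 kept the direction and call, 597 lost the call, 105 gained it and 63 changed sign. The lists' calls held in 884 comparisons and were lost in 98.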

Other observations

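The tests of the chow calls, the 3 tests of Kupffer cell markers other than the splits, the tests of detected genes, and the splits for the number of lists between diets were chosen after the results were seen, and the other splits before.

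Genes of fatty acid oxidation and its transcriptional control rose in part on FFC. Of 18 measured, 7 rose, 1 fell and 10 did not pass in wild-type livers (8 rose and 1 fell adjusted over the list alone, median log2 change 0.17, camera adjusted p = 0.0584), and 6 rose, 2 fell and 10 did not pass in knockout livers (7 rose and 2 fell adjusted over the list alone, median 0.39, camera adjusted p = 0.290). Vnn1, a pantetheinase under control of PPAR-alpha, rose from 45.8 ± 3.73 to 159.9 ± 25.3 CPM in wild-type and from 51.6 ± 10.4 to 147 ± 29.2 CPM in knockout livers (n = 3 per group), and Acot1, an acyl-CoA thioesterase, rose from 13.8 ± 0.279 to 43.5 ± 1.19 CPM in wild-type livers (log2 change 1.66, edgeR adjusted p = 4.1e-04). Of 9 genes of the oxidative stress response, 2 rose in wild-type livers (2 adjusted over the list alone, median 0.16, camera adjusted p = 0.638) and 4 rose and 1 fell in knockout livers (4 and 1 adjusted over the list alone, median 0.11, mean -0.19, camera adjusted p = 0.514), among them Srxn1, sulfiredoxin, from 22.1 ± 1.96 to 54.8 ± 0.575 CPM. With offsets for GC content and length 7 of the 8 called genes of fatty acid oxidation kept their call in wild-type and 3 of 8 in knockout livers. Outside the lists, Enho, which encodes the secreted peptide adropin, fell from 11.7 ± 2.43 to 0.456 ± 0.275 CPM in wild-type and from 27.1 ± 19.1 to 0.787 ± 0.144 CPM in knockout livers. Serpina1e, a serpin of the alpha-1-antitrypsin family, fell from 8515 ± 2999 to 371 ± 105 CPM and from 14090 ± 6447 to 918 ± 611 CPM, and the neurotrophin receptor Ntrk2 rose from 0.319 ± 0.247 to 20.3 ± 2.89 CPM in wild-type livers. In knockout livers on chow Ntrk2 had 1 to 3 counts over the group, and the ratio of its FFC level to its chow level was 399.6 (95% counting interval 136.5 to 1939).

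Lists of lymphocyte, neutrophil and bile duct markers did not pass camera between the diets, although several had a positive median in wild-type livers. There 1 of 5 neutrophil (median 0.74, camera adjusted p = 0.232), 1 of 11 T cell (0.84, 0.297) and 0 of 5 natural killer cell markers (0.55, 0.239) rose in edgeR. Among all 16283 tested genes 1427 rose by the same test. Of 9 B and plasma cell markers, 1 rose and 2 fell (0.979), and of 7 cholangiocyte markers 0 passed (median 0.79, camera adjusted p = 0.178). By fry, which asks whether a list's own genes move 1 way, the adjusted p was 0.0054 for T cell, 0.038 for neutrophil and 0.038 for cholangiocyte markers in wild-type livers, and 0.0018 for T cell and 0.0263 for B and plasma cell markers in knockout livers, where 3 of the 9 B and plasma cell markers rose and 0 fell (camera adjusted p = 0.242). In knockout livers the neutrophil list had a median of -0.51 and a mean of -0.06 while its test pointed up (camera adjusted p = 0.997). The clock list had a median of 0.23 while its test pointed down (0.878), and the female-biased list had a median of -0.96 and a mean of 0.50 (0.997). Between genotypes on FFC the T cell list had a median of -0.13 while its test pointed up (0.897), and in the interaction lipid-associated macrophage markers had a median of -0.61 and a mean of -0.01 (0.165) and the cytokine list a median of 0.16 with a test that pointed down (0.797). On chow the median of monocyte-derived markers was -0.07 as fitted and 0.15 with genes at 0 set to their bound.

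Kupffer cell markers were higher in knockout livers on FFC by camera with its preset correlation (adjusted p = 2.4e-12), and did not pass with an estimated correlation (adjusted p = 0.0751). On chow their median log2 change between genotypes was 0.40, and the list did not pass. In the interaction the list's median was 0.058 in absolute size, and 1 member, Marco, passed the edgeR test. A larger shift of the list on FFC than on chow was therefore not shown. A rise of all macrophage markers by the same amount is argued against by the list means on the log2 scale. The mean of the Kupffer list minus that of the general macrophage list was 1.05 ± 0.174 in knockout and 0.516 ± 0.147 in wild-type libraries (n = 3). The difference was 0.532 (SE 0.131, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The Kupffer mean includes Marco and Timd4, called in this same comparison, and the difference without them was not computed. The general macrophage mean includes Lyz2, whose locus drives the Cre, and the difference without Lyz2 was not computed either. The list medians, which depend less on single genes, changed by 0.549 for Kupffer and 0.12 for general macrophage markers. GC content and length trends as the cause are argued against by a median change of 0.433 with offsets, and a single library by a lowest median of 0.464 with 1 FFC library left out, against 0.549 with all, although it was 0.313 with a term for the replicate number. The real split was the 1 of 10 splits of the FFC libraries with a median change this large, and the highest other was 0.335, but 10 splits are too few for a share under 0.05. Whether Kupffer cells were more numerous or held more of these transcripts stays open and was not tested, since bulk counts do not separate the number of cells from the level in each.

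Genotype calls on chow numbered 1185 in the fit of all groups and 0 of these were kept when the chow libraries were fitted alone, where the median absolute log2 change of these genes went from 0.909 to 0.884 and the median SE from 0.221 to 0.275. Of 1097 of these genes tested there, 1091 had an unadjusted p under 0.05, and the larger SE and the fewer residual degrees of freedom were not separated. Whether the spread shared with the tighter FFC libraries made the calls stays undecided. Simulated chow groups without a difference gave 8 calls or fewer in the fit of all groups. That simulation drew each gene independently, without the GC content and length trends of the real chow libraries. It therefore does not show how many calls the shared spread could make in the real data. GC content and transcript length trends as the whole cause are argued against by 356 of the called genes that were called again with offsets, although the median absolute log2 change went from 0.909 to 0.571. These repeated calls came from the fit of all groups. With offsets in the chow libraries alone 0 genes were called, so the trends together with the shared spread stay open. A real effect of the genotype on chow was not tested apart from these.

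Fewer genes were detected in chow than in FFC libraries. Depth is argued against as the whole cause, since the lowest FFC library had 1165 more detected genes than the highest chow library at equal totals and 834 more at equal totals times normalization factors, which were lower in chow libraries. Transcripts lost at random when the libraries were made are a possible explanation. Genes at 0 in 1 library with at least 10 counts in both other replicates numbered 11 to 211 per chow library and 1 to 9 per FFC library. Lower depth and a wider spread between replicates, both found in chow libraries, also raise this number, so it cannot single out random loss. Wild-type chow replicate 2, with 11, was close to the FFC libraries yet had fewer detected genes than any of them at equal depth. A wider range of expressed genes in livers with more immune and stromal cells stays open as an untested biological explanation. The labels give no batch of library preparation. The library numbers in the titles run in blocks by group. They are 1 to 3 for wild-type chow, 4 to 6 for knockout chow, 7 to 9 for wild-type FFC and 13 to 15 for knockout FFC. The diet and the genotype contrasts may therefore both carry a difference between libraries along with the effect of diet or genotype.

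Other splits of the 6 libraries of a comparison were fitted as the real one was. For diet in wild-type livers 1 of 10 splits, the real one, gave as many genes (2734, highest other 0), for diet in knockout livers 1 of 10 (4312, highest other 0), for genotype on FFC 1 of 10 (3, highest other 1) and for genotype on chow 1 of 10 (1185, highest other 6), and 10 splits are too few for a share under 0.05 in each. For the lists between genotypes on FFC 7 of 10 splits, the real one included, gave at least as many as the real 8, and the highest other gave 13. Lists in such numbers were thus common in groupings that mix the genotypes, so their number is no evidence of a genotype difference. For the lists by diet 1 of 10 splits gave as many in wild-type livers (18, highest other 16) and 1 of 10 in knockout livers (16, highest other 11). Here too 10 splits are too few for a share under 0.05. For the diet the other splits, with 0 genes called by edgeR, gave 6 to 16 lists in wild-type and 3 to 11 in knockout livers by camera with its preset correlation.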
